A study of Mus musculus with 72 samples.

How the data were processed

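IMPLICON is bisulfite amplicon sequencing of imprinted regions. Reads are assigned to a parental genome by strain variants, so that each CpG has a methylation level per parental allele. Per the labels, DNA came from 5 brain areas (hippocampus, cerebellum, prefrontal cortex, hypothalamus and nucleus accumbens) and from lung, a control organ, of 8 female F1 mice of reciprocal BL6 and CAST crosses. The labels give the old mice as 101 or 103 weeks old, while the protocol text gives a range that begins above 101 weeks; the labels were used. The labels list 72 samples on 2 lanes. The 48 samples of lane 7651 have columns in the table used here, 1 library per mouse and tissue. The 24 samples of lane 7950 (hippocampus, cerebellum and lung again) were not used here, so the planned comparison of the lanes and the alternatives restricted to a lane were not run.

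The deposited table gives methylation as a percent, the methylated calls over all calls at 1 CpG on reads of 1 genome, with no further normalization. Its second block of deposited columns gives the count of calls behind each percent. Percent times coverage came to whole methylated calls within 0.000266 of a call. Per the submitters' processing notes, bcl2fastq 2.20, Trim Galore 0.6.6 and Bismark 0.14.4 were used on build GRCm38. The tool that split the reads by genome, and any filter on reads, are not given in the sources used here. Per the labels' protocols, each primer pair was amplified apart from bisulfite-converted DNA, the products were pooled, and a second PCR added the barcodes. No molecular identifier is mentioned in the labels, and whether PCR copies were removed is not known. Calls can therefore not be taken as independent molecules, and counting intervals cover counting error only.

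The table names its genomes 1 and 2. Genome 1 was taken as BL6, which the labels do not state, and alleles were turned into maternal and paternal with the cross in the labels. Feature names of the Dlk1-Dio3 and Igf2-H19 regions count upwards row by row and were pooled back to 1 region each. The table has 224 CpGs in 16 regions, of which 139 CpGs lie in the 10 regions tested. Of these, 7 are imprinted regions methylated on the maternal allele (Commd1/Zrsr1, Gnas, H13/Mcts2, Impact, Mest, Plagl1 and Snrpn) and 3 are non-imprinted controls (Klf4, Sox2ot and Prickle1). Gene positions came from a RefSeq table of the same build.

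A CpG entered with at least 50 calls on its allele, and the level of a region-allele (a region on 1 parental allele) is the mean over its CpGs. A region-allele was tested where at least 2 old and 2 young mice had a value, or at least 3 mice per tissue in the tissue comparison. These mouse minimums, and the centring that keeps a missing region from shifting a mouse's mean level, were set after the region values had been seen and before any test was run. The old minus young difference was fitted per tissue with limma 3.58.1 (R 4.3.3) on percent methylation, with the cross as covariate, two-sided, and Benjamini-Hochberg adjustment over the region-alleles of a class and tissue. The threshold was an adjusted p of 0.05. limma on percent was kept as the main test as planned. The edgeR 4.0.16 quasi-likelihood test on methylated and unmethylated calls was added after the data were seen, and its counts stand beside limma's.

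Mean levels per mouse were compared with an exact two-sided permutation test, for which 4 against 4 mice give 70 assignments and a smallest p of 0.0286. Maternal and paternal levels of the same mouse were compared with an exact sign-flip test, which gives 0.00781 at the smallest for 8 mice. Each brain area was compared with lung in limma with age and cross as covariates. The difference of an age effect between tissues was tested with limma on the within-mouse difference of the tissues. The cross effect is the cross coefficient of the age fit. The spread between mice was compared over the 35 splits of the mice. Single CpGs were fitted like regions with limma alone, and CpGs of 1 amplicon are read on the same molecules.

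The regions named in the text follow a rule written before the data were examined. For age they are all region-alleles past the threshold plus the 3 with the largest difference per tissue. For imprinting they are all regions, with values for the 2 largest and 2 smallest differences. For tissue and cross they are at most 5 past the threshold. Regions named outside this rule are said to be so. No region from the lists of somatic imprinted regions, age-marker CpGs or X-linked genes was among the tested regions.

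Libraries had 376 to 461238 calls, with a median of 62773. The numbers in the labels mark the same animal across tissues, so they pair the tissues. The correlation of the deviations of the same mouse, taken as a median per pair of tissues, ran from -0.17 to 0.85 with a median of 0.26 over 15 pairs. Alternatives were the coverage minimum (20, 100 and 200 calls), the logit scale, no cross covariate, a trend in the moderation, exact permutation, adjustment over all tissues, the median over CpGs, CpGs covered in every mouse, at least 3 CpGs, the mouse as a block and each mouse left out. Added after the data were seen were edgeR, a run without 2 end CpGs, and all alternatives for the control regions.

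The fits were tested on simulated data. Calls were drawn at the measured coverages, levels and spreads, and 2 region-alleles per simulation were shifted in the old mice. There were 25 simulations per tissue and shift. For the 10 or 11 imprinted region-alleles of a tissue, limma recovered 4 to 20% of shifts of 5 points, 36 to 68% of shifts of 10 points and 60 to 98% of shifts of 20 points. edgeR recovered 6 to 18%, 18 to 54% and 38 to 96%. With no shift, 11.3% of the limma simulations and 8% of the edgeR simulations of imprinted regions held a false call, above the 5% that the threshold aims at. For the 6 control region-alleles of a tissue, limma recovered 68 to 98% of shifts of 5 points, and 8.67% of simulations with no shift held a false call. Figures were drawn with matplotlib 3.10.9.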

Results

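Allele-resolved CpG methylation of imprinted regions was measured in 6 tissues of 8 female mice, to ask whether imprinted methylation holds in the aged brain. The 4 old mice were 101 weeks (mice 1 and 2, BL6 mother and CAST father) or 103 weeks old (mice 3 and 4, CAST mother and BL6 father). The 4 young mice were 8 weeks (mice 5 and 6, CAST mother) or 9 weeks old (mice 7 and 8, BL6 mother). These are the ages in the sample labels; the protocol text gives the old mice a range that begins above 101 weeks. Within an age group the cross therefore goes with a difference of 1 or 2 weeks.

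The 48 libraries, 8 per tissue, held 376 to 461238 calls. The hippocampus library of old mouse 3 held the 376 calls and had no CpG at the minimum of 50 calls, so hippocampus rests on 3 old mice. Young mouse 8 was the shallowest animal, with a median of 16171 calls per library and a range of 9785 to 21582. Medians of the other mice ran from 55565 to 82931 calls. Libraries of prefrontal cortex held a median of 147528 calls in old and 43272 in young mice (exact permutation p = 0.0857, adjusted 0.343), the lowest p of the 6 tissues. Adjustment over 6 tissues takes the smallest possible p of 0.0286 to 0.171, so a depth difference in 1 tissue alone could not have passed.

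The 7 imprinted regions carried high methylation on the maternal allele and low methylation on the paternal allele. Plagl1, which encodes a zinc finger transcription factor, differed most, with 91.0% ± 1.02 (SD, n = 7 mice) on the maternal and 4.46% ± 4.10 on the paternal allele. Commd1, whose intron holds the imprinted gene Zrsr1, had 90.3% ± 3.65 and 5.63% ± 1.61 (n = 8). The smallest differences were at Gnas, which encodes the stimulatory G protein alpha subunit, with 79.6% ± 5.76 and 12.3% ± 2.22 (n = 8), and at Mest, with 78.4% ± 7.00 and 12.1% ± 4.35 (n = 6). Snrpn, Impact and H13, the host gene of the imprinted retrogene Mcts2, lay between these, with mean differences of 81.0, 78.9 and 73.5 points. The levels of H13 here and below include an end CpG with 48.1% on the maternal and 48.6% on the paternal allele. Its other CpGs had 86.0 and 8.38%.

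The maternal level was the higher one in 237 of 238 pairs of region and library. The exception was Gnas in the prefrontal cortex of young mouse 5, with a difference of -6.48 points. By exact sign-flip tests, 5 regions passed adjustment in each of cerebellum, prefrontal cortex, hypothalamus, nucleus accumbens and lung, and 2 in hippocampus. Commd1, Impact and Plagl1 missed in hippocampus, with differences of 88.1, 81.8 and 89.2 points. The maternal level was the higher one there in each mouse with values (n = 5, 5 and 6). Their exact sign-flip p of 0.0625, 0.0625 and 0.0313 were the smallest that so few mice allow. Mest and Snrpn had values in too few mice to pass, with smallest exact permutation p of 0.0625 and 0.125 over all tissues. On build GRCm38 the amplicons lie on chromosome 10 from 13091188 to 13091361 (Plagl1), chromosome 11 from 22971952 to 22972139 (Commd1) and chromosome 18 from 12972868 to 12973155 (Impact). Those of H13 (152686786 to 152686970) and Gnas (174295708 to 174295954) lie on chromosome 2.

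**Figure D1:**
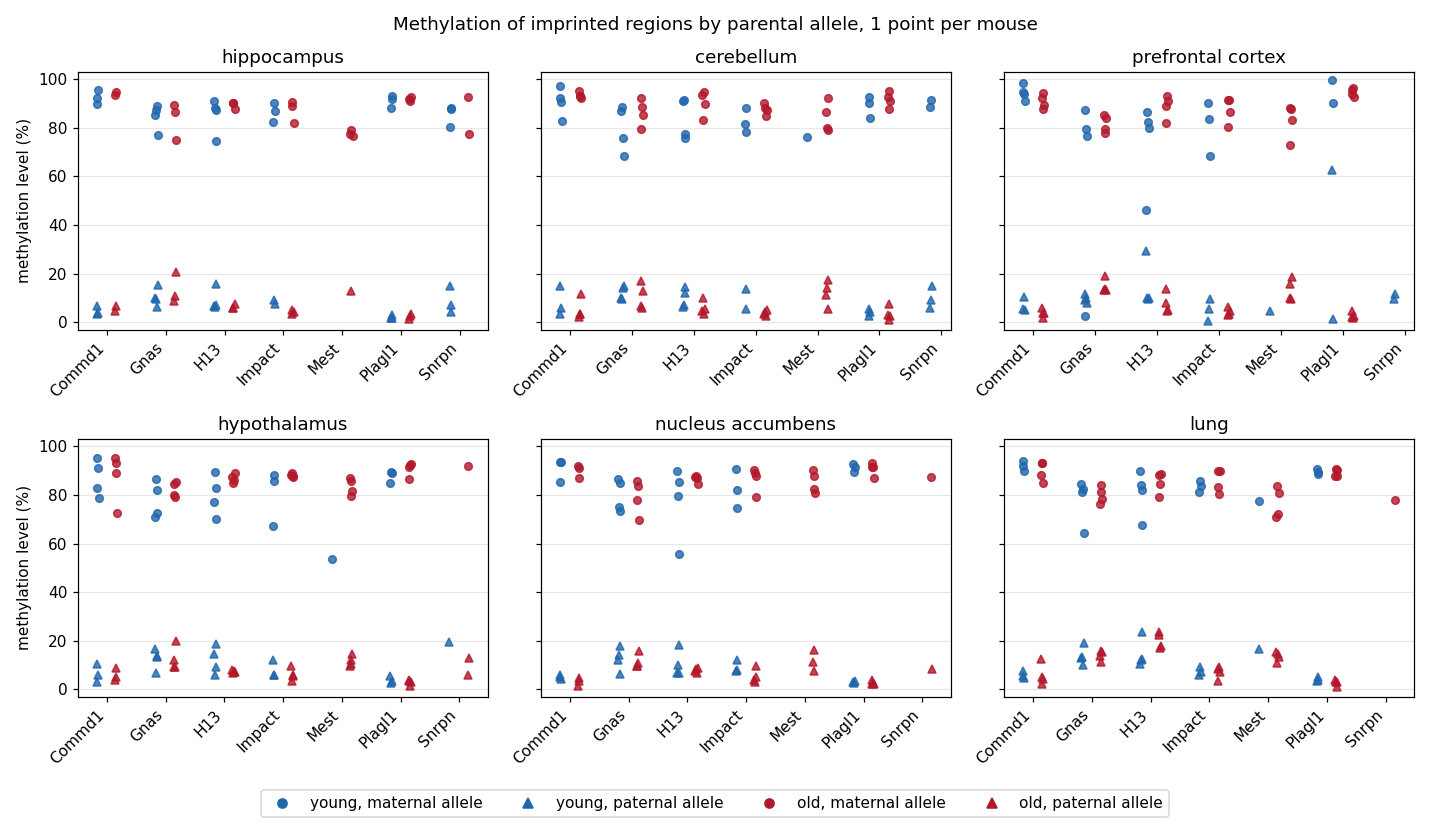
Methylation level (%) of each imprinted region in the 6 tissues, with 1 point per mouse, circles for the maternal and triangles for the paternal allele, blue for young and red for old mice. The maternal level is the higher one except at Gnas in the prefrontal cortex of young mouse 5, where Plagl1 (36.8 points) and H13 (16.7 points) also have their smallest difference of any library.

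The central comparison was old against young mice. No change with age was detected at a tested imprinted region-allele in any of the 6 tissues. The tests covered Commd1, Gnas, H13, Impact and Plagl1, and maternal Snrpn in hippocampus alone. Mest, and Snrpn elsewhere, had values in too few mice. At a coverage minimum of 20 calls some of these entered and passed, as given below. Of 61 tests with limma, 0 passed adjustment and 3 had an unadjusted p below 0.05, while edgeR on calls gave 0 and 1. The 3 were Gnas and H13 on the maternal allele in cerebellum and, named after its value was seen, Gnas on the paternal allele in prefrontal cortex. Maternal Gnas was 86.4% ± 5.32 in old and 79.8% ± 9.51 in young cerebellum (n = 4 and 4), a difference of 6.58 points (95% interval 0.676 to 12.5, limma adjusted p = 0.189, exact permutation p = 0.257). Paternal Gnas in prefrontal cortex was 14.7% ± 2.79 in old and 9.70% ± 1.55 in young mice (n = 4 and 4), and all 4 old mice lay above the young ones (limma adjusted p = 0.351, exact permutation p = 0.0286). In simulated data limma recovered 4 to 20% of shifts of 5 points and 36 to 68% of shifts of 10 points.

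In hippocampus the largest differences were 4.85 points at maternal H13, -4.07 points at paternal Impact and 3.57 points at paternal Gnas (limma adjusted p = 0.845 for each). The sign at paternal Gnas turned when mouse 4 was left out, to -1.16 points, and the difference was 7.03 points without mouse 8. In cerebellum they were 6.58 points at maternal Gnas, 6.27 points at maternal H13 and -5.69 points at paternal Impact (adjusted p of 0.189, 0.189 and 0.302). In hypothalamus they were 7.06 points at maternal Impact, 6.97 points at maternal H13 and -4.80 points at paternal H13 (adjusted p = 0.605 for each). In nucleus accumbens they were 9.03 points at maternal H13, 3.59 points at maternal Impact and -3.26 points at paternal Impact (adjusted p = 0.781 for each). With 1 mouse left out, maternal H13 ran from 0.594 (without mouse 8) to 9.26 points (without mouse 4) in hippocampus. In cerebellum maternal Gnas ran from 2.63 to 8.75 and maternal H13 from 3.11 to 8.33 points (lowest without mouse 1, highest without mouse 4). In hypothalamus maternal Impact ran from 1.15 (without mouse 5) to 11.5 points, maternal H13 from 3.90 (without mouse 8) to 9.89 points and paternal H13 from -2.55 (without mouse 8) to -6.91 points, the farthest each without mouse 6. In nucleus accumbens maternal H13 ran from 1.48 (without mouse 8) to 13.4 points (without mouse 7), and maternal Impact from 0.200 (without mouse 6) to 8.29 points (without mouse 5).

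The widest values were in prefrontal cortex, where 1 library set them. Paternal Plagl1 differed by -29.8 points, maternal Gnas by 20.2 points and maternal H13 by 15.0 points (limma adjusted p of 0.351, 0.384 and 0.351). Young mouse 5 had 62.8% at paternal Plagl1, 2.65% at maternal Gnas and 46.1% at maternal H13 in this library. Without mouse 5, maternal Gnas differed by 0.0677 points (34.0 without mouse 6) and maternal H13 by 4.70 points, and paternal Plagl1 had too few young mice. In the same setting maternal Impact in prefrontal cortex, named after its value was seen, was higher in old mice by 11.4 points (limma adjusted p = 0.00466). Mouse 8 had no Impact value there, so this compares 4 old mice with young mice 6 and 7 alone. With the mouse as a block over all tissues, paternal Plagl1 in prefrontal cortex passed (limma adjusted p = 0.00298), in a fit that includes that library.

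In lung the largest difference was at H13 on the paternal, normally unmethylated allele. It was 20.2% ± 3.13 in old and 14.6% ± 6.14 in young mice (n = 4 and 4), a difference of 5.57 points (95% interval -0.0947 to 11.2, limma adjusted p = 0.531, exact permutation p = 0.2). Maternal H13 differed by 4.24 points (limma adjusted p = 0.965), and by 0.427 points without mouse 8 and 1.50 points without mouse 2. Young mouse 8, with a median of 86 calls per CpG, had 23.8% and the other young mice 10.4 to 12.4%. Without mouse 7 the difference at paternal H13 was 3.45 points. Without mouse 8 the paternal H13 level rose with age by 8.00 points (95% interval 4.75 to 11.2, limma adjusted p = 0.00716). The exact permutation p was then 0.0286, the smallest that 4 against 3 mice allow.

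**Figure D2:**
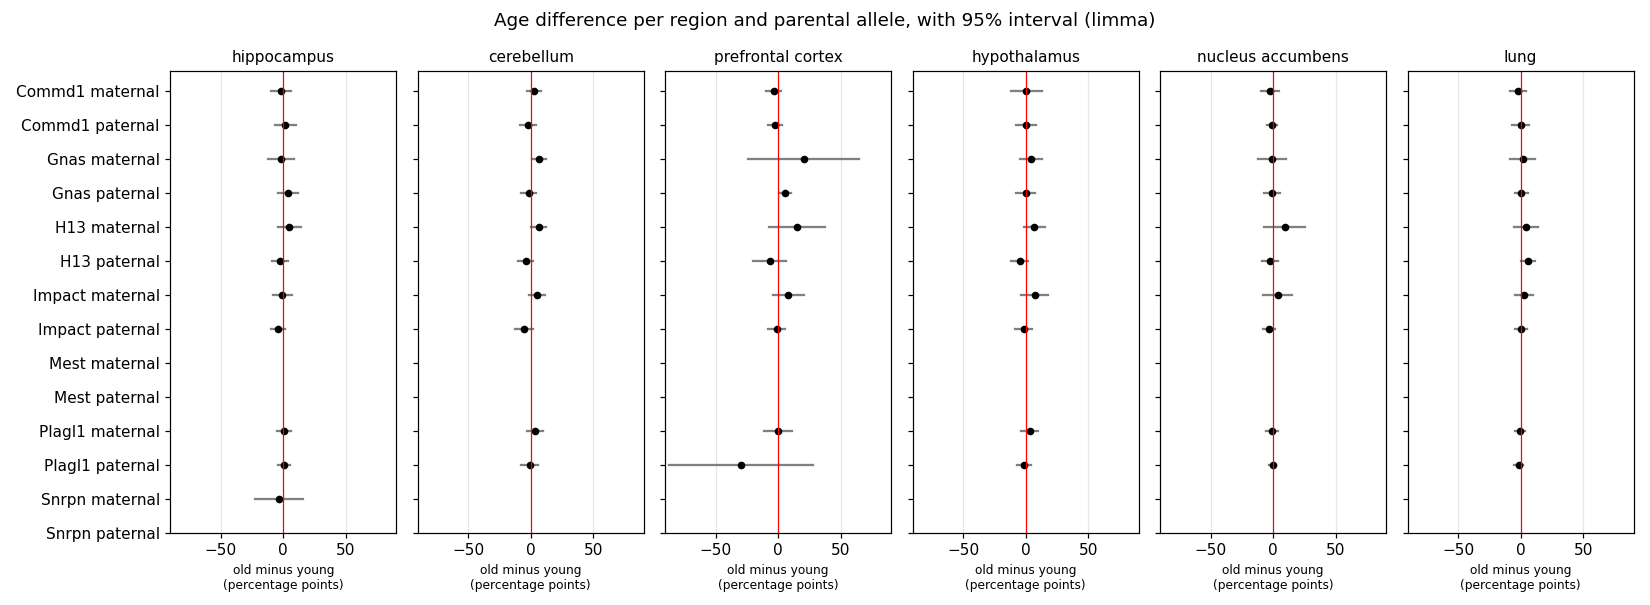
Old minus young difference in methylation (percentage points) per region and parental allele in each tissue, with the limma estimate as a point and its 95% interval as a line; region-alleles with too few mice have none. No difference passed adjustment, and the widest intervals are those of Plagl1, Gnas and H13 in prefrontal cortex.

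Mean levels over the imprinted regions tested for age were compared by exact permutation, where a smallest p of 0.0286 in 1 tissue alone is adjusted to 0.171 and cannot pass. Mouse 8 entered these means with fewer regions than the others. Its libraries had a median of 7.5 region-alleles at the coverage minimum, controls included, against 16 to 18.5 in the other mice. The mean maternal level was 88.7% ± 0.520 in old and 81.3% ± 9.47 in young prefrontal cortex (n = 4 and 4), a difference of 7.41 points (exact permutation p = 0.0571, adjusted 0.343). Without mouse 5 it was 3.54 points, and without mouse 6 it was 12.5 points. The mean difference between maternal and paternal alleles was higher in old mice in each tissue, by 3.01 points in hippocampus, 8.76 in cerebellum, 14.5 in prefrontal cortex, 8.50 in hypothalamus, 7.13 in nucleus accumbens and 3.34 in lung (adjusted exact permutation p of 0.429 to 0.857). With 1 mouse left out it ran from -1.31 to 5.92 points in hippocampus (highest without mouse 4), 4.72 to 11.6 in cerebellum (mouse 6), 4.14 to 18.1 in prefrontal cortex (mouse 8), 5.14 to 12.3 in hypothalamus (mouse 6), 0.979 to 10.5 in nucleus accumbens (mouse 5) and -2.51 to 5.56 in lung (mouse 5). The lowest value came without mouse 8 in each tissue but prefrontal cortex, where it came without mouse 5. The sign turned only in hippocampus and lung, where the values without old mouse 1 and old mouse 2 were 0.860 and 1.91 points.

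Drift between animals can also show as spread. The median log2 ratio of the SD between mice, old over young, was -0.08 in hippocampus, -0.64 in cerebellum, -1.40 in prefrontal cortex, -0.58 in hypothalamus, -0.27 in nucleus accumbens and 0.54 in lung. Of the 35 splits of the mice, 31, 12, 13, 18, 27 and 14 gave a ratio as far from 0 in these tissues. The sign rested on single mice in several tissues. The ratio was 0.26 in hippocampus without mouse 8 and 0.34 in hypothalamus without mouse 5. It was 0.27 in nucleus accumbens without mouse 6 and -0.14 in lung without mouse 2. At a coverage minimum of 200 calls the ratio in prefrontal cortex was 0.66. At single CpGs, 0 of at least 120 CpG-alleles per tissue passed adjustment with limma (edgeR was not run on single CpGs). At an unadjusted p below 0.05 there were 2 in hippocampus, 16 in cerebellum, 6 in prefrontal cortex, 1 in hypothalamus, 2 in nucleus accumbens and 15 in lung. Without mouse 8, 19 CpG-alleles passed in lung.

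The control regions are not imprinted and had like levels on both alleles. Klf4, a pluripotency factor gene, had 1.50% ± 0.502 on the maternal and 1.62% ± 0.332 on the paternal allele (n = 8). Sox2ot, a long noncoding RNA gene that overlaps Sox2, had 3.74% ± 0.495 and 3.49% ± 0.748, and Prickle1, a planar cell polarity gene, had 91.6% ± 2.43 and 91.8% ± 1.31. The level of Prickle1 includes an end CpG near 50%, covered in 38 libraries on the maternal and 36 on the paternal allele, without which the other CpGs had 94.7 and 94.8%. Of 36 age tests of control region-alleles, limma called 3 and edgeR 2.

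Paternal Sox2ot in lung rose from 1.10% ± 0.148 in 3 young mice to 3.60% ± 0.497 in 4 old mice, by 2.52 points (limma adjusted p = 0.00377, edgeR adjusted p = 2.06e-05). All 4 old mice lay above the 3 young ones, with an exact permutation p of 0.0286, the smallest possible. Of the 6 control region-alleles in lung it was the only 1 with an unadjusted limma p below 0.05 (edgeR called 2). Maternal Sox2ot, the other allele of the same amplicon, thus did not reach even that with limma. With the mouse as a block over all tissues the difference was 2.47 points and missed the threshold (adjusted p = 0.110). Exact permutation in place of limma could not keep the call, since adjustment over 6 tests takes its p of 0.0286 to 0.171. Prickle1 in prefrontal cortex fell by 2.60 points on the maternal and by 2.54 points on the paternal allele (limma adjusted p = 0.0175 for both). With the mouse as a block the differences were -2.75 and -2.54 points and missed the threshold (adjusted p = 0.141 for both). edgeR called neither (adjusted p of 0.437 and 0.235), and neither passed without the end CpG of the amplicon (adjusted p of 0.239 and 0.749). Both passed at a coverage minimum of 100 calls, with -4.84 and -5.49 points. The end CpG had a median of 117.5 maternal and 116.5 paternal calls, so that minimum sets in which libraries it counts. Its part in these values was not tested, and they add no weight to an age effect. With 1 mouse left out, 0 of the Prickle1 alleles passed without mouse 1, 3, 4 or 7, and 1 without mouse 2 or 5, while the differences lay between -1.28 and -3.70 points.

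**Figure D3:**
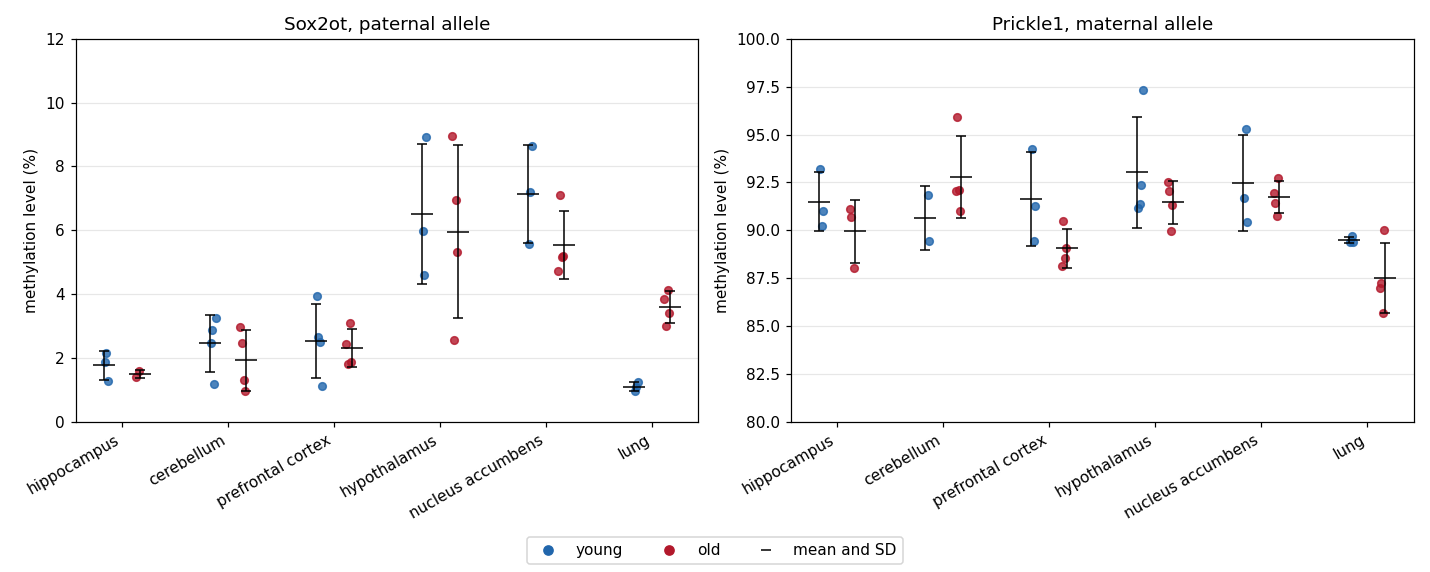
Methylation level (%) of paternal Sox2ot and maternal Prickle1 in the 6 tissues, with 1 point per mouse and the mean with SD in black; both axes are cropped to the range of the values. Paternal Sox2ot is 1.10% in young and 3.60% in old lungs on average.

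Each brain area was compared with lung over both ages. Paternal H13 was called lower in 4 of the 5 brain areas than in lung, where it was 17.4% ± 5.40 (n = 8). It differed by -9.81 points in hippocampus, -9.47 in cerebellum, -7.75 in hypothalamus and -8.29 in nucleus accumbens (limma adjusted p of 0.00891, 0.00406, 0.0184 and 0.00542). The direction held in 7 of 7, 8 of 8, 7 of 8 and 8 of 8 mice. The call in hypothalamus was lost when mouse 1, 2, 3 or 4 was left out, at differences between -6.48 and -7.47 points (adjusted p of 0.0618 to 0.0842). In prefrontal cortex the difference was -6.19 points (limma adjusted p = 0.283), and paternal H13 lay above lung in 1 of 8 mice. Its level there was 11.2% ± 7.90 (n = 8), with the library of young mouse 5 included. In that area limma passed 0 region-alleles and 3 had an unadjusted p below 0.05 (edgeR was not run on tissues).

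Both alleles of Prickle1 were more methylated in cerebellum, hypothalamus and nucleus accumbens than in lung, by 3.34 to 4.39 points (limma adjusted p of 0.00157 to 0.0486), and by 3.24 to 3.62 points without the end CpG (adjusted p of 0.000502 to 0.00540). Both alleles of Sox2ot were more methylated in hypothalamus and nucleus accumbens, by 2.90 to 3.95 points (limma adjusted p of 0.00157 to 0.0184). Maternal Sox2ot was 6.90% ± 1.56 in hypothalamus and 2.95% ± 0.909 in lung (n = 7 and 7). The counts past adjustment were 1 in hippocampus, 3 in cerebellum, 5 in hypothalamus and 5 in nucleus accumbens, of 17 or 18 region-alleles, and 2 in hypothalamus without mouse 1. Maternal Prickle1 missed the threshold in hypothalamus without mouse 1 and in cerebellum when any 1 of mice 1 to 6 was left out, and paternal Sox2ot in hypothalamus without mouse 1, 5 or 7. With the mouse as a block, cerebellum kept 1 call and the Prickle1 alleles there missed the threshold (adjusted p of 0.129 and 0.0501). At a coverage minimum of 100 calls the Prickle1 calls ended in all 3 brain areas, with differences of 1.57 to 3.63 points (limma adjusted p of 0.176 to 0.408).

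At paternal H13 the age effect differed from that in lung in 3 of the 5 brain areas. The age difference minus that in lung was -8.11 points in nucleus accumbens (limma adjusted p = 0.000719), -8.56 points in hippocampus (adjusted p = 0.0129) and -10.4 points in hypothalamus (adjusted p = 0.0493). In cerebellum the difference was -9.70 points (adjusted p = 0.0514) and in prefrontal cortex -12.4 points (adjusted p = 0.499), or -6.47 points without mouse 5. The value in cerebellum passed without mouse 7 or 8 (adjusted p of 0.0252 and 0.0284). Within a mouse, paternal H13 in nucleus accumbens lay -12.3 points from lung in old and -4.23 points in young mice (n = 4 and 4). The 5 comparisons share the same lung libraries and so are not independent, and the age difference in lung did not itself pass (adjusted p = 0.531). Between hippocampus and cerebellum, without lung, the age effects at paternal H13 differed by 1.15 points (adjusted p = 0.933). No other region-allele was called in these comparisons, and for hippocampus minus cerebellum limma called 0 of 16 with 2 at an unadjusted p below 0.05 (edgeR was not run on these differences). On the logit scale all 3 H13 calls were lost (adjusted p of 0.238 in hippocampus, 0.0868 in hypothalamus and 0.10 in nucleus accumbens). There the call in nucleus accumbens was paternal Sox2ot (adjusted p = 0.00362), which was also called in prefrontal cortex (adjusted p = 0.0475). With 1 mouse left out, the adjusted p in hypothalamus passed only without mouse 6 and missed the threshold without each of the others, at differences between -8.48 and -10.8 points. That in hippocampus missed the threshold without mouse 2, 5 or 8, at differences between -7.86 and -8.73 points.

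**Figure D4:**
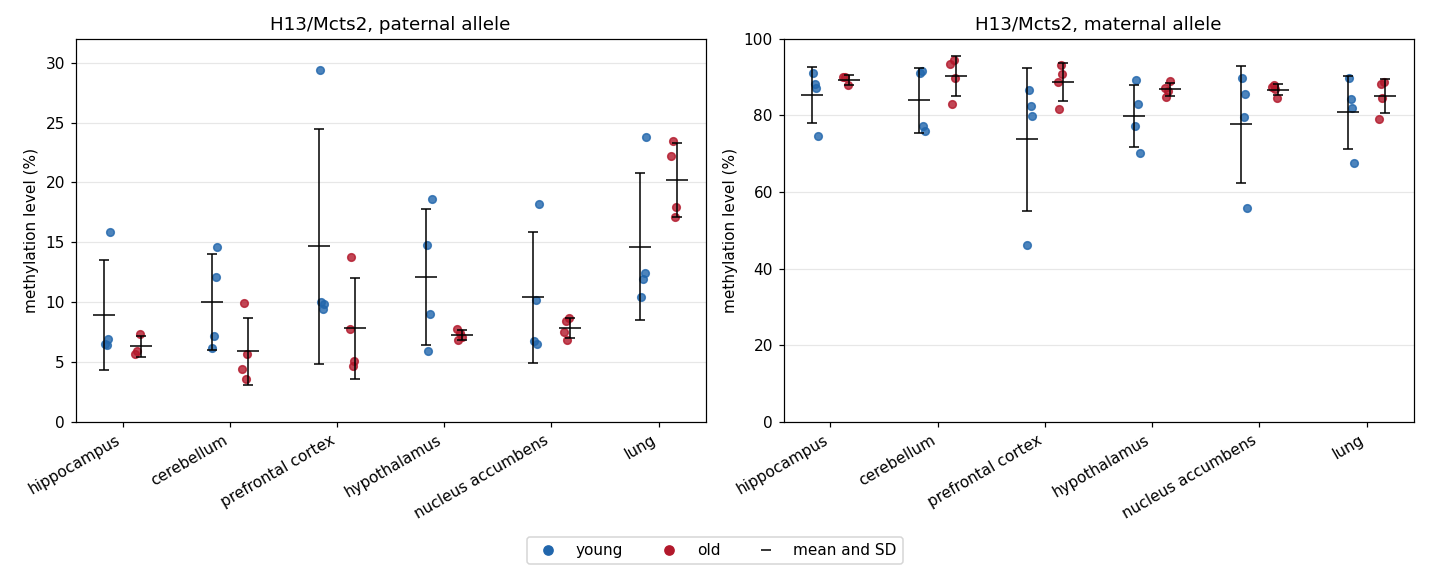
Methylation level (%) of H13 on the paternal (left) and maternal (right) allele in the 6 tissues, with 1 point per mouse, blue for young and red for old mice, and the mean with SD in black. The paternal level of the 4 old lungs lies between 17.1 and 23.5%, and that of the young lungs between 10.4 and 23.8%.

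A difference between the reciprocal crosses on 1 parental allele can lie in the strain of that allele or in the cross itself, which cannot be told apart here. In cerebellum the maternal allele was lower in mice with a BL6 mother at H13, with 82.4% ± 7.99 against 91.7% ± 2.07, and at Gnas, with 79.0% ± 9.93 against 87.3% ± 1.71 (n = 4 and 4). The fitted differences were -9.29 and -8.31 points (limma adjusted p of 0.0275 and 0.0341). edgeR called 0 in cerebellum with 1 at an unadjusted p below 0.05, and exact permutation gave p of 0.114 and 0.143. Both missed the threshold when mouse 2, 3, 5, 6, 7 or 8 was left out, at differences between -7.93 and -9.39 points for H13 and between -5.40 and -9.05 points for Gnas. In the other tissues limma and edgeR called 0. An unadjusted p below 0.05 occurred 1 time, with limma in lung.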

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

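The tests of the prefrontal cortex library, of H13 in lung and of splits with the mouse as block in this part were chosen only after the results were seen; the counts over other splits were planned before. Of 95 groups of 4 or more mice, 10 had a mouse far from the others, where chance gives about 5% of independent groups. The groups overlap, since a region enters the mean levels and these the allelic difference, and the 10 come from 4 libraries, so this count cannot be set against that share. Mouse 8, the shallowest animal, accounts for 7 of them, mouse 5 for 2 and mouse 3 for 1.

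In the prefrontal cortex library of young mouse 5, maternal Gnas was 2.65% against 76.8 to 87.4% in the other young mice, and maternal H13 was 46.1% against 79.9 to 86.6%. Few template molecules amplified in this library may account for this: 4 CpG-alleles lay over 50 points from the median of their own allele, and no other library had 1 (highest 0). They lay at maternal Impact and at paternal Klf4, Prickle1 and Snrpn, and not at Gnas or H13. A shift of all CpGs of an amplicon together cannot show in this count. The count thus sets the library apart, and few templates at Gnas and H13 themselves were not tested. Swapped parental labels are argued against by Impact, where maternal minus paternal was 89.7 points in the same library. A change carried by the animal is argued against by the other tissues of mouse 5, where maternal Gnas was 70.7% at the lowest. A change in this brain area of this mouse was not tested and stays open.

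Paternal H13 was higher in old lungs than in 3 of the 4 young lungs, and its age effect in hippocampus, hypothalamus and nucleus accumbens differed from that in lung by -8.56, -10.4 and -8.11 points. Low depth is argued against for the level above brain, since 13 brain libraries with as many calls reached 14.8% at most and the old lungs 17.1% at least. For old against young lungs depth cannot be told apart from age, since the old lungs had fewer calls at H13 (exact permutation p = 0.343, mouse 8 included). Mouse 8 had the shallowest lung library, with 9785 calls over all regions, and the highest paternal H13 in lung, at 23.8%. The other young lungs held 60363 to 140066 calls and the old lungs 34417 to 73403. Depth at H13 without mouse 8 was not tested. Reads assigned to the wrong allele would raise the other 4 paternal levels, whose mean differed by -1.17 points (95% interval -5.78 to 3.45). They would also lower maternal H13, which differed by 4.24 points (-7.61 to 16.1). Without mouse 8 the values were 0.259 (-3.45 to 3.97) and 0.427 points (-8.38 to 9.24). Such reads stay open, since paternal H13 minus that mean differed by 6.74 points with an exact permutation p of 0.0857 (8.45 points and 0.0571 without mouse 8). An effect of age in lung stays open as a hypothesis, and it was found and tested on the same 8 mice.

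Mouse 8 stood apart from the other young mice at paternal H13 in lung, with 23.8% against 10.4 to 12.4%. It also did so at paternal H13 in hippocampus, with 15.8% against 6.40 to 6.93%. Its mean paternal level was 12.4% in hippocampus and 15.2% in lung, and its mean maternal level was 70.3% in lung. These means rest on few regions, since mouse 8 had 6 region-alleles at the coverage minimum in hippocampus and 5 in lung, controls included. In lung its imprinted regions were Gnas and H13 alone. The mean difference between alleles of mouse 8 was 66.5 points in hippocampus and 55.0 points in lung. In the old hypothalamus, mouse 3 had a mean difference of 80.2 points against 81.4 to 81.5 in the other old mice.

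Signal also appeared in regions outside the main measurement. The calls of Dlk1-Dio3 and Igf2-H19, all under the coverage minimum, gave mean paternal levels of 84.7% and 72.1% (n = 8 mice, calls pooled per mouse). Mrpl10 had 74 of 88 calls methylated (84.1%, Wilson 95% interval 75.0 to 90.3) in 1 library. Muc20 had 33 of 38 (86.8%, 72.7 to 94.2) over 22 libraries. A feature named Igf2r, whose positions lie in Mtcl1, had 18 of 60 (30.0%, 19.9 to 42.5) over 11 libraries.

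Other splits of the same mice were fitted for each count of calls. For the age comparison of imprinted regions the real count was 0 in each tissue and so all 35 splits gave as many; the highest other split gave 3 in hippocampus, 2 in cerebellum and lung, and at most 1 elsewhere. For CpGs the real count was also 0 in each tissue (35 of 35). The highest other splits gave 35 in hippocampus (mice 1, 2 and 7 against the rest), 13 in prefrontal cortex (mice 1, 2, 5 and 7), 10 in nucleus accumbens (mice 1, 3, 5 and 7), 3 in cerebellum, 2 in lung and 1 in hypothalamus. In hippocampus 17 of these calls were CpGs of maternal and 17 of paternal H13, in prefrontal cortex 12 were of paternal Plagl1 and in nucleus accumbens 9 of maternal Gnas. Since CpGs of 1 amplicon are read on the same molecules, such counts show mice that stand apart mostly at 1 region, and a wider structure of the samples was not tested.

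The shares of splits were not adjusted for the number of counts made. For the control regions, no other split gave as many calls in prefrontal cortex (1 of 35 splits, real 2, highest other 1). Both calls there are alleles of the Prickle1 amplicon, with exact permutation p of 0.0857 and 0.114, and edgeR called neither, so chance is not excluded. It could not be excluded in lung (5 of 35 splits, real 1, highest other 2), and the real count was 0 in hippocampus, cerebellum, hypothalamus and nucleus accumbens (35 of 35, highest other 1, 1, 1 and 3). For the cross it could not be excluded in cerebellum (3 of 35, real 2, highest other 3), and the real count was 0 elsewhere (35 of 35, highest other 3 in hippocampus). Against lung, tissue labels were swapped within mice. Few swaps gave as many calls in hypothalamus (1 of 100 splits, real 5, highest other 3) and nucleus accumbens (2 of 100, real 5, highest other 5). The same held with the mouse as block (1 of 100, real 5, highest other 4, and 2 of 100, real 5, highest other 5). In both areas the 5 calls are paternal H13 and both alleles of Prickle1 and of Sox2ot. Chance is unlikely for each count taken alone, but with unadjusted shares it is not excluded. In cerebellum the fit without the block gave 1 of 100 (real 3, highest other 2), but with the block chance could not be excluded (5 of 100, real 1, highest other 5). In hippocampus the fits differ, with 7 of 64 without the block (real 1, highest other 2) and 3 of 64 with it (real 1, highest other 4), so chance is not excluded there. In prefrontal cortex the real count was 0 in both (100 of 100, highest other 2 and 1). For the age effects that differ from lung, chance could not be excluded from the count of calls in hippocampus (4 of 35, real 1, highest other 2), hypothalamus (5 of 35, real 1, highest other 3) or nucleus accumbens (5 of 35, real 1, highest other 2). The real count was 0 for hippocampus minus cerebellum, cerebellum minus lung and prefrontal cortex minus lung (35 of 35, highest other 1, 4 and 2).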

How the results depend on the processing

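Chosen only after the data were seen were edgeR on calls, the run without the 2 end CpGs and all alternatives for the control regions; the others were planned before the data were examined. Of 1623 values under alternatives, 1382 stayed the same. For counts this means equal or within 1.5 times, and for tests the same direction and side of the threshold, whether called or not. Of the others, 79 lost a call, 4 gained one, 77 counts moved by over 1.5 times in the settings and 50 with a mouse left out, and 31 values changed sign. The cause was not tested unless given. The alternatives by lane were not run. Depth kept Mest and Snrpn, with medians of 49.5 and 29 calls per CpG and allele, out of most age tests. At the measured depths and with these mice, limma recovered 4 to 20% of simulated shifts of 5 points at imprinted and 68 to 98% at control regions; depth and number of mice were not varied. In the counts below the value in the report stands in brackets.

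With the mouse as replicate block (the number is the same animal), imprinted age calls were 1 (0) in prefrontal cortex, control calls 0 (2) in prefrontal cortex and 0 (1) in lung, and calls of cerebellum against lung 1 (3). The block changed no other call count.

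At a coverage minimum of 20, imprinted age calls were 2 (0) in hypothalamus (maternal Mest and Snrpn) and 1 (0) in lung (paternal Mest), control calls 1 (2) in prefrontal cortex, cross calls in cerebellum 1 (2), age-effect differences of hypothalamus minus lung 0 (1) and CpG calls in hypothalamus 23 (0). Maternal Mest and Snrpn in hypothalamus were higher in old mice by 23.2 and 21.2 points (limma adjusted p of 0.000228 and 0.00222). Paternal Mest in lung differed by -20.9 points (limma adjusted p = 0.0118). The main age comparison did not test these region-alleles. The mean paternal age difference in lung turned to -5.19 points and the lung log2 SD ratio to -1.0.

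At 100 calls, imprinted calls were 1 (0) in lung (paternal H13), control calls 1 (0) in hippocampus and 2 (0) in nucleus accumbens, and cross calls in cerebellum 0 (2). Calls against lung were 4 (1) in hippocampus, 1 (3) in cerebellum, 2 (0) in prefrontal cortex, 2 (5) in hypothalamus and 3 (5) in nucleus accumbens. Age-effect differences from lung were 0 (1) in hippocampus, 1 (0) in cerebellum and 0 (1) in hypothalamus, and CpG calls in lung 18 (0). The mean paternal difference in prefrontal cortex turned to 0.713 points and the mean allelic difference in lung to -1.83 points.

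At 200 calls, imprinted calls were 1 (0) in lung, control calls 0 (2) in prefrontal cortex and 0 (1) in lung, and cross calls in cerebellum 1 (2). Calls against lung were 4 (1), 1 (3), 1 (0), 1 (5) and 2 (5) in hippocampus, cerebellum, prefrontal cortex, hypothalamus and nucleus accumbens. Age-effect differences from lung were 0 (1) in hippocampus, 1 (0) in cerebellum, 1 (0) in prefrontal cortex and 0 (1) in hypothalamus, and CpG calls in lung 17 (0). In lung the mean maternal difference turned to -0.495 and the allelic difference to -5.08 points. The mean paternal difference turned to 0.898 in prefrontal cortex and 0.143 in nucleus accumbens, and the log2 SD ratio in prefrontal cortex to 0.66. Mouse 8 drops out of H13 in lung at 100 and 200 calls.

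On the logit scale, control calls were 0 (2) in prefrontal cortex and 2 (1) in lung, calls of cerebellum against lung 1 (3), and cross calls in cerebellum 0 (2). Age-effect differences from lung were 0 (1) in hippocampus, 1 (0) in prefrontal cortex and 0 (1) in hypothalamus. In nucleus accumbens the count stayed at 1, but the call was paternal Sox2ot and not paternal H13, and that in prefrontal cortex was paternal Sox2ot too. The mean paternal difference in lung turned to -0.128 (logit units) and the hippocampus log2 SD ratio to 0.25.

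With the median over CpGs, control calls were 0 (2) in prefrontal cortex and 2 (1) in lung, calls of prefrontal cortex against lung 1 (0), and cross calls in cerebellum 1 (2). Age-effect differences were 1 (0) for hippocampus minus cerebellum and 1 (0) for cerebellum minus lung. The mean paternal difference in lung turned to -0.125 points and the hippocampus log2 SD ratio to 0.47. The control calls in prefrontal cortex were also 0 (2) without the cross covariate, with a trend, with exact permutation, with adjustment over all tissues, with CpGs in every mouse, with edgeR and without the end CpGs. Those in lung were 0 (1) with exact permutation and with CpGs in every mouse (where, as at 200 calls, paternal Sox2ot had too few mice to be tested), and 2 (1) with edgeR and without the end CpGs. edgeR gave 0 (2) cross calls in cerebellum. Without the end CpGs, calls of hippocampus against lung were 3 (1), age-effect differences of hippocampus minus cerebellum 1 (0) and CpG calls in cerebellum 1 (0).

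In old or in young mice alone, 0 regions passed for the parental difference in each tissue, against 2 in hippocampus and 5 elsewhere, since 4 mice cannot reach the threshold.

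With 1 mouse left out, imprinted age calls ran from 0 to 1 in prefrontal cortex (1 without mouse 5) and in lung (1 without mouse 8). Control calls ran from 0 to 1 in hippocampus, 0 to 2 in prefrontal cortex and 1 to 2 in lung. CpG calls ran from 0 to 1 in cerebellum and 0 to 19 in lung (19 without mouse 8). Parental calls ran from 0 to 2 in hippocampus and 0 to 5 in cerebellum, with fewer mice to flip. Calls against lung ran from 1 to 2 in hippocampus, 0 to 2 in prefrontal cortex (2 without mouse 5) and 2 to 5 in hypothalamus. Age-effect differences ran from 0 to 2 for hippocampus minus cerebellum, 0 to 4 for hippocampus minus lung and 0 to 1 for cerebellum and hypothalamus minus lung. Cross calls in cerebellum ran from 0 to 2. The age difference at paternal Gnas in hippocampus ran from -1.16 to 7.03 points. Mean maternal differences ran from -0.578 to 3.81 in hippocampus and -0.666 to 5.10 in lung, mean paternal ones from -2.23 to 0.582 and -0.606 to 1.85, and allelic ones from -1.31 to 5.92 and -2.51 to 5.56. The log2 SD ratio ran from -1.41 to 0.26 in hippocampus, -1.70 to 0.34 in hypothalamus, -1.03 to 0.27 in nucleus accumbens and -0.14 to 0.75 in lung. The age effect at paternal H13 in nucleus accumbens minus lung passed with each mouse left out.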

Other observations

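All tests in this part were chosen only after the results were seen. The paternally methylated regions Dlk1-Dio3 and Igf2-H19, which control the imprinting of Meg3 and of H19 and Igf2, had too few calls per CpG for the main comparisons. With calls pooled per mouse over all tissues, Dlk1-Dio3 was 84.7% on the paternal and 18.1% ± 16.2 on the maternal allele (n = 8), a difference of 66.6 ± 25.1 points. Mouse 8 set the maternal spread, with 57.7% on the fewest maternal calls of the 8 mice against 9.83 to 16.4% in the others, and had 66.5% on the paternal allele. Igf2-H19 was 72.1% ± 21.9 and 22.1% ± 15.4, with 27.7% and 0% in mouse 8. The paternal level was the higher one in 8 of 8 mice at both (exact sign-flip permutation p = 0.00781, the smallest possible). Old against young mice gave exact permutation p of 0.114 to 0.886 for these levels.

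A higher difference between maternal and paternal alleles in old mice over all tissues was tested as a hypothesis with each mouse's mean over tissues. It was 81.0 ± 1.60 points in old and 73.3 ± 7.66 points in young mice (n = 4 and 4), with an exact permutation p of 0.0571. The value misses the threshold and does not exclude a difference. Young mice 8 and 5 had 63.3 and 71.5 points, while young mice 6 and 7 had 80.4 and 78.1 points. The old mice had 78.7 to 82.2 points. The mean of mouse 5 includes its prefrontal cortex library, with 36.9 points. Without mouse 8 the difference between old and young mice fell to 4.34 points with an exact permutation p of 0.0857. Leaving out mouse 5 or that library was not tested.

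The last covered CpG of the H13 amplicon had 48.1% on the maternal and 48.6% on the paternal allele, and that of the Prickle1 amplicon 49.8% and 51.8%. A base set by the assay and not by the template may account for this. The spread between libraries was at most 1.14 times the binomial spread of the calls. Mixed reads of both parental alleles are argued against at Prickle1, where the level lay at least 43.0 points below the mean of the other CpGs on either allele. No biological explanation was tested.

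Calls at Klf4 came more often from genome 1 than from genome 2 in 47 of 47 libraries, with a median log2 ratio of 1.04. An unnamed region on chromosome 8 had 0 of 320 calls methylated, which allows a level of up to 0.938% and covers counting error only.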
